A study of Mus musculus with 6 samples.

How the data were processed

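Per the labels' protocols, poly(A)-selected RNA from the ischaemia-reperfusion region of mouse hearts was sequenced in 6 libraries, 3 from mice with ischaemia-reperfusion alone (IR) and 3 from mice that also received trimethylamine N-oxide (TMAO) in their drinking water (TMAO+IR). Groups and replicate numbers were taken from the sample titles. In the deposited table the TMAO+IR columns carry the prefix T-IR, which was matched to the only group of the series other than IR. The labels number the libraries within each group without naming animals, so p-values measure only the spread between these libraries, which may be technical. Per the submitters' processing notes, the tools and build were fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, DESeq2, edgeR and the GRCm38 build. The notes give no role or order for these tools, and the tool behind the deposited p-values is not given in the sources used here.

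The authors deposited one table of 149 genes. It holds whole-number read counts per gene and library as deposited by the authors, without normalization. It also holds FPKM values per library from the authors' quantification, printed to 2 decimals. The authors' group means are means of the 3 FPKM values of a group, with a mean of 0 replaced by 0.001. The deposited log2 fold change equals the log2 ratio of these means, with a largest difference of 7.98e-09 on recalculation. The deposited p-value and its adjusted value (FDR) come from the authors' own test over all the genes they tested. Every listed gene had an FDR of at most 0.0487 and an absolute log2 fold change of at least 1.00 in the authors' deposited table. The list was therefore selected on the same difference that it describes. In the authors' deposited table, the ratio of FDR to p-value of the top gene implied that about 12721 genes were tested, and that of the last listed gene implied a rank of at most about 570. The values of genes outside the list were not analysed here.

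Because the list holds only selected genes, library sizes could not be taken from column sums. They were recovered from the ratio of count to FPKM in 86 genes with at least 1 FPKM in every library. Absolute sizes came from 12 of these genes with a single annotated transcript. The recovered sizes ranged from 18371383 fragments in TMAO+IR replicate 1 to 22442709 in IR replicate 3. The counts of the listed genes summed to between 73268 and 232484 per library. All 149 Ensembl gene identifiers matched GENCODE release M21 on GRCm38, with the same symbols, and all are annotated as protein-coding. The annotation release used by the authors is not given in the sources used here. Counting of overlapping genes and of near-identical gene copies is not described either, so values of gene families such as Slfn, Trim30 and Ifi200 members are uncertain. GC content and length were taken from the longest annotated transcript of each gene.

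Counts were tested with edgeR 4.0.16 (quasi-likelihood test, 2-sided, R 4.3.3) with the recovered library sizes, no further scaling and no filter. Benjamini-Hochberg adjustment was made over the 149 listed genes, with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. The moderation gave every gene the spread of the common trend. The SE and the edgeR p-values therefore hardly reflect the replicate spread of an individual gene. This holds also where no SD of the FPKM values is given beside the SE, as for many genes below. A call lost in edgeR with a wider adjustment thus need not mean that the gene varied much between libraries. Likewise a call kept there need not mean that the gene varied little, so these calls do not rank genes by evidence. The test was tested on simulated data with the real library sizes and 1000 genes. It recovered 97% of the genes changed by 2 on the log2 scale and 56% of those changed by 1, and called 0.25% of the unchanged genes. Because selection precedes this test, 12721 unchanged genes were also simulated 20 times, the 149 smallest p-values kept and those genes refitted alone. Before selection a median of 0 genes passed, and after selection a median of 149 of 149. Adjusted p-values of the refit are therefore not independent evidence, and the authors' FDR is the only adjustment here that covers the genes outside the list. A gene is said to have risen or fallen where it passed both tests.

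There were 33 gene lists, holding 1035 different genes, fixed before the data were examined. They cover stress, mitochondrial, metabolic and immune pathways, and markers of the cell types that the tissue or its surroundings could hold. Lists with at least 5 listed members were tested for direction against the other listed genes with Fisher's exact test. A count adjusted over a list alone could not be made, since p-values of unlisted members were not used here. The rule for named genes was fixed before the data were examined. It names the gene of the series title (Fdxr), with Eif2ak3, Eif2s1, Atf4 and Ddit3. It adds the 10 highest and the 10 lowest log2 fold changes among genes whose libraries did not overlap between groups and whose higher group mean was at least 1 FPKM, without predicted genes. Up to 4 members with the smallest adjusted p of each list with at least 3 listed members, and the 5 genes with the highest mean FPKM, complete it. Other listed members of small gene lists, and the genes of the closing section outside this rule, were chosen after their values were seen. The values of a further listed gene are not reported here. Alternatives were DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 0.1), TMM scaling within the list, a minimum mean of 50 counts, the replicate number as a block, leaving out each library, stricter thresholds, and removal of predicted genes. Adjustment over the implied number of tested genes, and lists with at least 3 members, were added after the data were seen.

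No 2 libraries held the same counts in more than 6 of the 149 genes. The floor for a gene at 0 counts covers counting error only. The bootstrap intervals resample genes and the permutations shuffle them, so both treat genes as independent.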

Results

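The series compared the transcriptome of the reperfused region of the heart between mice with and without TMAO preconditioning. TMAO is an oxidation product of trimethylamine, which gut bacteria form from choline and carnitine. In male C57BL/6 mice the left anterior descending coronary artery was tied for 45 min and then released for 24 h. The TMAO+IR mice drank water with 0.12% TMAO for 4 weeks before this procedure and during it. Each group had 3 libraries, with recovered depths of 20682234, 21989073 and 22442709 fragments in IR and 18371383, 21534598 and 20827122 in TMAO+IR. The listed genes held between 0.33% (IR replicate 3) and 1.08% (TMAO+IR replicate 2) of these fragments. Only the 149 genes that the authors listed as changed were analysed, so every count below describes that list and not the transcriptome. Fold changes are TMAO+IR over IR from counts, with the SE on the log2 scale, and expression levels are FPKM as mean ± SD (n = 3 per group).

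The comparison addresses how TMAO preconditioning alters gene expression in the injured myocardium. Of the 149 listed genes, 122 rose and 27 fell. Cyp1a1, a cytochrome P450 that metabolises xenobiotics and is induced through the aryl hydrocarbon receptor, rose most among the genes that met the naming rule. It went from 0.86 ± 0.28 to 10.9 ± 2.07 FPKM, a 12.7-fold rise (log2 3.66 ± 0.40), with an FDR of 5.47e-40 in the authors' deposited table. Myh7, the beta isoform of cardiac myosin heavy chain, rose 4.60-fold (SE 0.43 on the log2 scale), from 9.24 ± 3.13 to 37.8 ± 16.2 FPKM. Its FDR was 6.09e-09 in the authors' deposited table. Cyp1a1 (ENSMUSG00000032315) lies on chromosome 9 at 57687928 to 57703824 of GRCm38, and Myh7 (ENSMUSG00000053093) on chromosome 14 at 54970684 to 54994626. Pi15, a secreted peptidase inhibitor, rose 3.21-fold (log2 1.68 ± 0.34), and Inhba, which encodes the subunit of activin A, rose 3.24-fold (log2 1.69 ± 0.34). Among the most abundant listed genes, Thbs1 (thrombospondin 1) went from 92.0 ± 44.6 to 231 ± 56.0 FPKM and the scaffold gene Akap12 from 60.8 ± 13.9 to 154 ± 30.6 FPKM. With edgeR p-values adjusted over the implied number of tested genes, Thbs1 (adjusted p = 0.246) and Akap12 (0.233) lost their calls, and Cyp1a1, Myh7, Pi15 and Inhba passed. In the authors' deposited table the FDR was 0.00239 for Thbs1, 3.18e-06 for Akap12, 3.71e-07 for Pi15 and 0.00167 for Inhba.

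**Figure D1:**
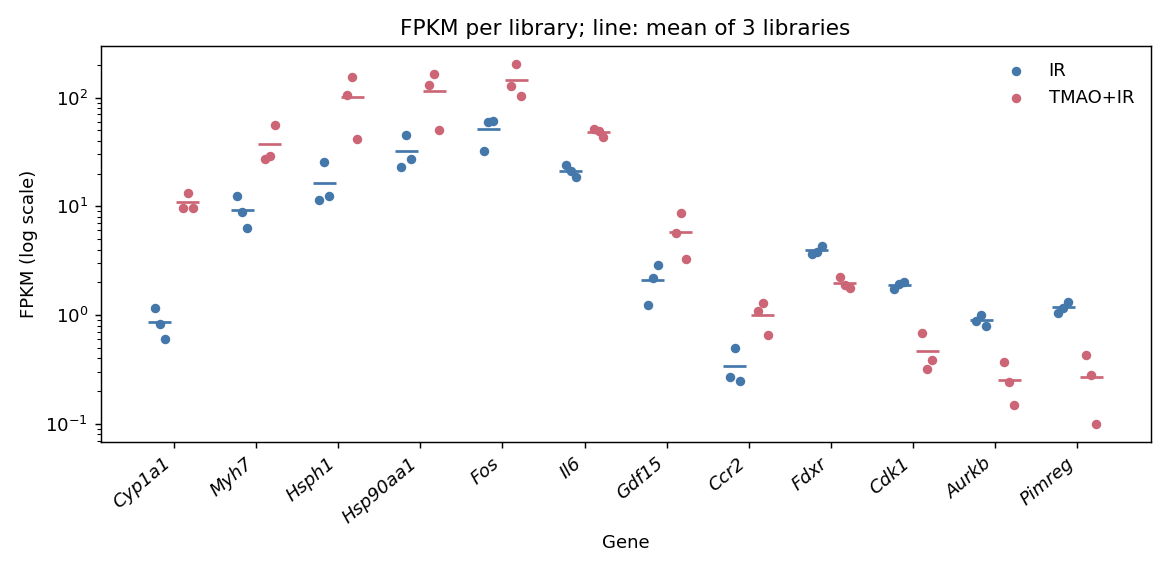
FPKM (log scale) of 12 named genes in each of the 3 IR (blue) and 3 TMAO+IR (red) libraries; dots are libraries and horizontal lines are group means. The libraries of the groups do not overlap in any of these genes, and Cyp1a1 goes from a mean of 0.86 to 10.9 FPKM while Fdxr goes from 3.93 to 1.96.

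The series title names the PERK and eIF2α stress pathway and the mitochondrial enzyme FDXR, ferredoxin reductase, which passes electrons to ferredoxin for iron-sulfur cluster and steroid synthesis. Fdxr fell from 3.93 ± 0.36 to 1.96 ± 0.24 FPKM (log2 -0.999 ± 0.33), and the libraries of the groups did not overlap. This change stands at the 2-fold limit of the list, and its FDR was 0.0065 in the authors' deposited table. In the refit with edgeR its adjusted p was 0.295 when adjusted over the implied number of tested genes, so the call was lost there. That p hardly reflects the spread of Fdxr itself. Fdxr (ENSMUSG00000018861) lies on the minus strand of chromosome 11 at 115268024 to 115277050, and its longest annotated transcript is 1948 bp with 60.0% GC. It was the only listed member of the 27 genes of the ferredoxin and iron-sulfur cluster list. Eif2ak3, which encodes PERK, Eif2s1, which encodes eIF2α, Atf4 and Ddit3 are not among the 149 genes and were not analysed here. Of the 48 genes of the integrated stress and unfolded protein response list, 2 were listed and both rose. They were Gdf15, a stress-induced cytokine, which rose 2.80-fold (log2 1.48 ± 0.33), and Slc7a11, the cystine transporter, which rose 2.32-fold (log2 1.22 ± 0.32). No listed gene belonged to the lists for oxidative phosphorylation (78 genes), the mitochondrial genome (15), the tricarboxylic acid cycle and glycolysis (36), or mitochondrial dynamics and mitophagy (29).

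Immediate early genes, which encode transcription factors induced within minutes of a stimulus, had the most listed members among the 33 gene lists. All 8 listed members of 31 rose, namely Fos, Fosl1, Jun, Egr1, Egr3, Nr4a2, Nr4a3 and Klf6. Fos rose 2.84-fold (log2 1.51 ± 0.43), Egr1 2.38-fold, Egr3 2.37-fold, Fosl1 2.42-fold and Nr4a2 2.16-fold. Fosl1 was the only one of these 8 whose scaled counts overlapped between groups. The direction of this list did not differ from that of the other listed genes, of which 114 rose and 27 fell (Fisher's exact test, 2-sided, p = 0.352, the only list large enough for the planned test). With all 8 members higher, no smaller p was possible upward, so the test could not show an upward skew. Adjusted over the implied number of tested genes, none of these 8 passed in edgeR (adjusted p from 0.0816 for Fos to 0.613 for Klf6). All 3 listed heat shock genes of 29 rose as well. Hsph1, a large heat shock protein, rose 5.69-fold (log2 2.51 ± 0.44), Hsp90aa1, the inducible cytosolic HSP90, 3.70-fold (log2 1.89 ± 0.43), and the co-chaperone gene Dnaja1 2.44-fold (log2 1.28 ± 0.42). Of these 3, Dnaja1 did not pass with that wider adjustment (edgeR adjusted p = 0.293). These genes varied widely within the TMAO+IR group, with 101 ± 57.3 FPKM for Hsph1 against 16.5 ± 7.81 in IR, and 115 ± 58.1 for Hsp90aa1 against 32.0 ± 12.1. Without TMAO+IR replicate 2, Egr1 (log2 0.95), Nr4a2 (0.77), Dnaja1 (0.86), Jun (0.88) and Nr4a3 (0.92) no longer passed the refit and Hsph1 stood at 1.90. Klf6 no longer passed without TMAO+IR replicate 1 (1.04), nor Nr4a3 without IR replicate 1 (0.98). Without TMAO+IR replicate 2 the median log2 fold change of the 11 early and heat shock genes was 1.05, against 1.27 with all libraries.

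Of the 52 cytokine and chemokine genes, 4 were listed and these 4 rose, as did the 3 listed of 39 interferon genes. Neither list differed in direction from the other listed genes (Fisher's exact test, 2-sided, p = 1 for both, with a minimum list size chosen after the data were seen). Since most listed genes rose, lists of 4 or 3 members that all rose could not differ upward, so this test could not decide. Il6 went from 21.3 ± 2.59 to 48.0 ± 4.45 FPKM (2.18-fold, log2 1.13 ± 0.40), Lif rose 2.38-fold, the alarmin gene Il33 2.37-fold and the neutrophil chemoattractant gene Cxcl5 2.18-fold. The FDR of Il6 was 6.22e-07 in the authors' deposited table. Its edgeR p adjusted over the implied number of tested genes was 0.462, but that p hardly reflects the spread of Il6 itself. None of the 4 cytokine genes passed there (lowest adjusted p 0.0996, for Lif, in edgeR). The interferon genes were Iigp1 (2.34-fold), Ifi204 (2.09-fold) and Ifit1 (2.03-fold), and none of the 3 passed with that wider adjustment (edgeR adjusted p from 0.252 to 0.462). Their FDR in the authors' deposited table ran from 1.83e-05 (Iigp1) to 0.00837 (Ifi204). With TMM scaling within the list, which moves the whole list down, none of these 7 genes passed, and the log2 values of Ifi204 and Ifit1 were -0.01 and -0.04. Without TMAO+IR replicate 1, Ifit1 no longer passed the refit (log2 0.82). The neutrophil marker list held 2 listed genes, Mmp8 (2.07-fold) and Slfn4 (2.78-fold), and the monocyte and macrophage list held Ccr2 and Chil3. Ccr2, the chemokine receptor of inflammatory monocytes, rose 2.81-fold (log2 1.49 ± 0.34) from 0.34 ± 0.139 to 1.01 ± 0.325 FPKM. Chil3, a product of alternatively activated macrophages and neutrophils, rose 2.86-fold (log2 1.51 ± 0.33). With the wider adjustment Slfn4, Ccr2 and Chil3 passed and Mmp8 did not (edgeR adjusted p = 0.462). The FDR in the authors' deposited table was 2.46e-07 for Slfn4, 0.0280 for Ccr2, 0.00826 for Chil3 and 0.00382 for Mmp8. The other members of these marker lists, of 32 and 41 genes, were not analysed here.

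In the oxidative stress and ferroptosis list, 4 of 37 genes were listed and all rose. Acsl4, which loads polyunsaturated fatty acids onto coenzyme A, rose 2.23-fold, the transferrin receptor gene Tfrc 2.33-fold and Ptgs2, which encodes cyclooxygenase 2, 2.34-fold. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose 1.64-fold in counts (log2 0.71 ± 0.35), with a log2 fold change of 1.07 from FPKM in the authors' deposited table. Cybb passed narrowly, lost its call without IR replicate 2, IR replicate 3, TMAO+IR replicate 1 or TMAO+IR replicate 2 (log2 0.67, 0.60, 0.75 and 0.66). With TMM scaling within the list, which lowers every listed gene, its log2 value was -0.32. From the list for complement, coagulation and fibrinolysis, Cfb (2.21-fold), the platelet chemokine gene Ppbp (2.28-fold) and the prothrombinase gene Fgl2 (2.32-fold) rose. None of these 4 and 3 genes passed in edgeR when adjusted over the implied number of tested genes. Their FDR in the authors' deposited table ran from 1.31e-06 (Tfrc) to 0.0233 (Cybb). Fgl2 lost its refit call without IR replicate 3 (log2 1.05) or without TMAO+IR replicate 1 (1.07), and Thbs1 without IR replicate 3 (1.11). Thbs1 (2.52-fold) and Tnc (2.50-fold) were the listed members of the 54 matrix and fibroblast genes. Runx1 (2.07-fold) stood beside Myh7 in the list of cardiac stress genes and lost its call without TMAO+IR replicate 2 (log2 0.87), the apoptosis gene Pmaip1 rose 3.61-fold, and the venular endothelial gene Ackr1 rose 2.55-fold. With the wider adjustment Tnc (edgeR adjusted p = 0.0816) and Runx1 (0.281) lost their calls as well, and Pmaip1 and Ackr1 passed. In the authors' deposited table the FDR was 0.00227 for Tnc, 0.0239 for Runx1, 0.00895 for Pmaip1 and 0.0218 for Ackr1. Pmaip1 and Ackr1 rest on few counts, with IR means of 10.3 and 20.7.

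**Figure D2:**
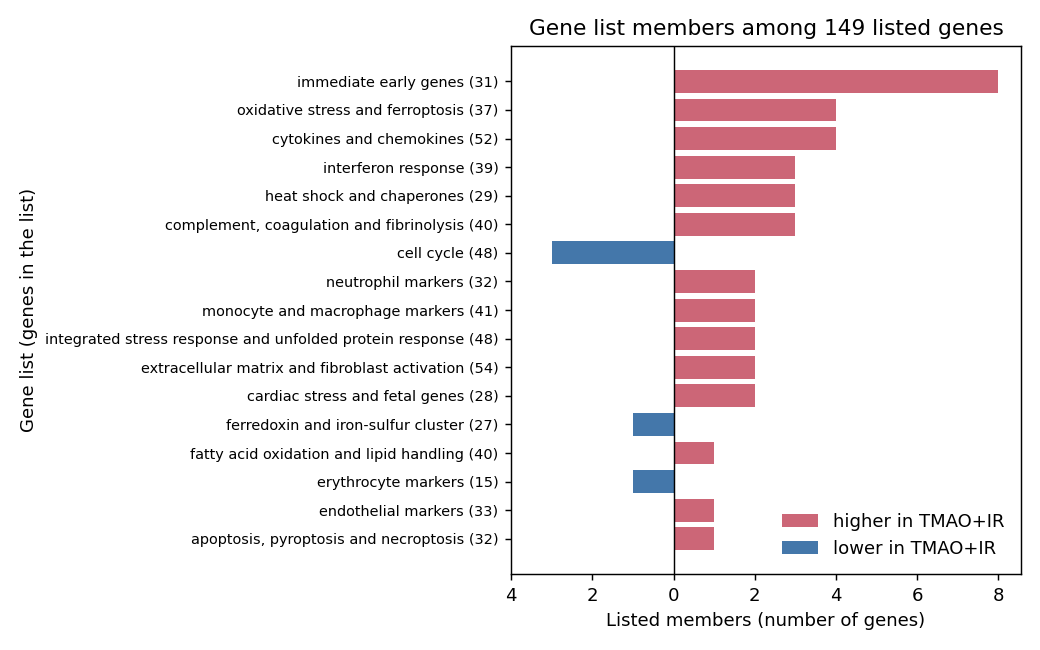
Number of listed genes from each of the 17 gene lists with at least 1 listed member, drawn to the right where higher (red) and to the left where lower (blue) in TMAO+IR; the number after each name is the size of the list. The immediate early list has 8 higher members and the cell cycle list 3 lower members; TMM scaling within the listed genes lowers all of them by about 1.03 on the log2 scale, and Cybb, Ifi204 and Ifit1 then change sign.

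Of the 48 cell cycle genes, 3 were listed and all 3 fell. Cdk1, the kinase that drives entry into mitosis, went from 1.90 ± 0.13 to 0.46 ± 0.19 FPKM (log2 -1.92 ± 0.37). Aurkb, a kinase of chromosome segregation, went from 0.90 ± 0.11 to 0.25 ± 0.11 FPKM (log2 -1.84 ± 0.40), and Spc24, a kinetochore component, from 4.62 ± 0.11 to 2.10 ± 0.38 FPKM (log2 -1.24 ± 0.33). Pimreg, a mitotic regulator outside the lists, had the lowest log2 fold change under the naming rule, -2.09 ± 0.42. With lists of at least 3 listed members, a minimum chosen after the data were seen, the cell cycle list was the only one of 7 whose direction differed from that of the other listed genes (Fisher's exact test, p = 0.0054, adjusted p = 0.038). The test treats the 3 cell cycle genes as independent, though they may change together in the same libraries. The remaining lists tested held only higher members, and at their sizes the test could not show an upward difference. With a minimum mean of 50 counts Cdk1 and Aurkb drop out, and this call cannot be made. Other genes that fell were Bicdl1, a dynein adaptor (log2 -1.44 ± 0.34), Sfrp2, a modulator of Wnt signalling (log2 -1.35 ± 0.35), Armc2 (log2 -1.24 ± 0.34) and Shld1 (log2 -1.22 ± 0.35). Ctf1, which encodes the cardiac cytokine cardiotrophin 1, fell by 1.21 on the log2 scale, Pfkfb1, a regulator of glycolysis, by 1.19 and the serine protease gene Hpn by 1.14. Adjusted over the implied number of tested genes, Armc2, Shld1, Ctf1, Pfkfb1 and Hpn lost their calls (edgeR adjusted p from 0.0574 to 0.149), and Cdk1, Aurkb, Spc24, Pimreg, Bicdl1 and Sfrp2 passed. The FDR in the authors' deposited table ran from 2.81e-05 (Armc2) to 0.0462 (Hpn) in the genes that lost their calls. In those that passed it ran from 0.00227 (Cdk1) to 0.0406 (Sfrp2), so passing here does not rank these genes. The anion exchanger gene Slc4a1, the only listed erythrocyte marker of 15, went from 0.34 ± 0.135 to 0.11 ± 0.044 FPKM.

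Of the 33 lists, 16 had no listed member. These included the markers of cardiomyocytes, smooth muscle and pericytes, lymphocytes, adipocytes, skeletal muscle, atrium, mesothelium, lung and thymus, and nerve. The circadian clock, the hypoxia and glucocorticoid response, and choline and methylamine metabolism also had none. Absence from the list means that a gene missed either limit of the list, was not among the about 12721 genes tested by the authors, or was not analysed here. It does not show that the level of the gene was equal in both groups.

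In the refit with edgeR all 149 genes passed an adjusted p of 0.05, in the same direction as in the authors' deposited table. Adjusted over the 12721 genes that the authors' deposited table implies, 50 passed, 38 higher and 12 lower, among them 15 of the 43 named genes. With TMM scaling within the list, which moved the median log2 fold change of the list by -1.03, 7 higher and 27 lower genes passed, with only Cyp1a1 and Hsph1 among the named higher genes. A count adjusted over each list alone was not made, since the unlisted members were not analysed here. Scaled counts of the groups did not overlap in 145 of the 149 genes, where chance gives 10% for 3 against 3 in genes that were not selected. The genes that rose and those that fell also differed in their transcripts. The longest annotated transcript had a median GC content of 44.6% and a median length of 4073 bp in the 122 higher genes, against 53.8% and 1950 bp in the 27 lower genes. Both differences gave the smallest p that 100000 permutations can give (permutation test, 2-sided, p = 1e-05, adjusted p = 2e-05 over 4 tests). The permutations treat genes as independent, which members of gene families such as Slfn and Trim30 may not be, so these p-values may be too small. The remaining tests set log2 fold change against each property among the 122 higher genes and did not pass. Spearman rho was -0.0019 for GC (permutation test, adjusted p = 0.984) and -0.0573 for length (adjusted p = 0.707). The medians of all 21951 annotated protein-coding genes were 48.7% and 2882 bp.

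**Figure D3:**
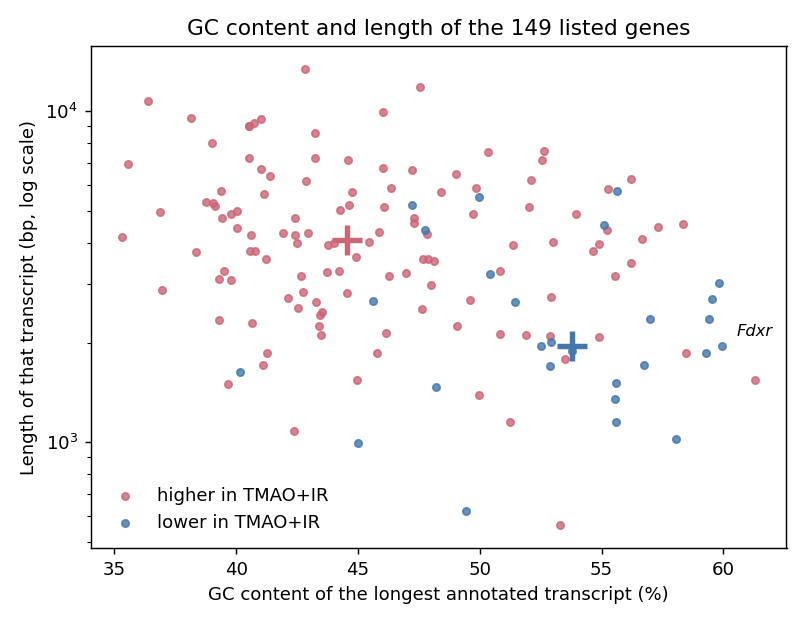
GC content (%) and length (bp, log scale) of the longest annotated transcript of the 122 genes higher (red) and 27 genes lower (blue) in TMAO+IR; crosses mark the group medians. The higher genes centre on 44.6% GC and 4073 bp and the lower genes, with Fdxr at 60.0% and 1948 bp, on 53.8% and 1950 bp.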

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

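The alternatives were planned, except adjustment over the implied number of genes and lists with at least 3 members. Of 149 genes past the threshold, DESeq2, limma on FPKM and the replicate block each called 149, and the 141 genes left without predicted genes all passed. With at least 50 counts 116 of 117 passed, with 17 of the 27 lower genes, since fewer genes were tested. Leaving out 1 library gave 117 (without TMAO+IR replicate 2) to 148 (without IR replicate 2) genes. Same-numbered libraries had correlations of deviation of -0.32, 0.33 and -0.08 over 117 genes, and only replicate 2 matched best with its own number. The labels name no pairs. These few correlations, over genes selected on the group difference, cannot show whether the block describes pairs. Adjustment over the implied 12721 genes left 50 (38 higher, 12 lower), a strict figure since unlisted genes with small p-values do not enter the ranks. TMM scaling within the list left 34 (7 higher, 27 lower), because it centres a list chosen for its change. It reversed 16 of the 122 higher genes, among the named ones Cybb (-0.32), Ifi204 (-0.01) and Ifit1 (-0.04). Of 43 named genes, Cybb also lost its call with at least 50 counts and in 4 of the 6 leave-one-out fits. Thbs1, Fgl2, Ifit1, Egr1, Dnaja1 and Nr4a2 lost theirs in at least 1 of these. The cause of these losses was not tested. No gene list passed the planned direction test under any alternative. In the main setting that test could not show an upward skew in the only list tested, since all its members were already higher. With lists of at least 3 members 1 list passed (cell cycle), a call that cannot be made with at least 50 counts, where Cdk1 and Aurkb drop out. No filter was the main setting and a pseudocount of 1 did not apply to counts, so neither was run as an alternative. Since selection alone yields a median of 149 passing genes in simulation, agreement between tools here shows no stability of the list. Depth limits the genes under about 50 counts, such as Ccr2, Aurkb, Pimreg, Pmaip1, Ackr1, Aim2 and Has2.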

Other observations

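The tests of scaling factors, of TMAO+IR replicate 2, of leukocyte markers, of annotation terms and of GC and length within groups were chosen after the result was seen. Further listed genes are given here as single genes, picked after their values were seen and without a test for enrichment. Has1 (2.41-fold) and Has2 (2.62-fold), the hyaluronan synthases, rose, as did Ugdh (2.28-fold), which makes their substrate UDP-glucuronate, and Tnfaip6 (2.45-fold), which binds hyaluronan. Ugdh lost its call without TMAO+IR replicate 1 (edgeR adjusted p = 0.0617). Cd274, which encodes the checkpoint ligand PD-L1, rose 2.35-fold and the costimulatory gene Cd80 2.29-fold. Cyp1b1, like Cyp1a1 induced through the aryl hydrocarbon receptor, rose 2.01-fold from 4.13 ± 1.52 to 8.26 ± 1.01 FPKM, and lost its call without TMAO+IR replicate 2 (log2 0.92). Nlrc5 (2.65-fold), Aim2 (3.69-fold) and Tlr9 (2.15-fold) rose, as did Herc6 (2.38-fold), Samd9l (2.01-fold) and Trim30a (2.15-fold), although with TMM scaling within the list the log2 value of Samd9l was -0.02. Adjusted over the implied number of tested genes, Has2, Nlrc5 and Aim2 passed in edgeR, and Has1, Ugdh, Tnfaip6, Cd274, Cd80, Cyp1b1, Tlr9, Herc6, Samd9l and Trim30a did not (adjusted p from 0.0518 for Herc6 to 0.804 for Cyp1b1). The FDR in the authors' deposited table ran from 0.000187 (Nlrc5) to 0.0487 (Aim2) in the genes that passed. In those that did not it ran from 5.46e-05 (Cd274) to 0.0413 (Tlr9). The 12 listed genes annotated to the innate immune response were all higher, without a difference in direction from the other listed genes (Fisher's exact test, adjusted p = 0.776). With all 12 higher, no smaller p was possible upward, so the test could not show an upward skew.

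Some values depend on how abundance was computed. In counts, 10 listed genes lay below a 2-fold change. Fdxr, Art5, Pde4b, Sema6d, Sntb2, Far1 and Gla missed 2-fold narrowly, and Ano10 had a log2 fold change of -0.90. Csf2rb was 1.68-fold higher in counts and 2.58-fold in FPKM, and Cybb 1.64-fold and 2.09-fold. The highest log2 fold change of the authors' deposited table, 9.32, belongs to the predicted gene Gm4737. It had 0 counts in all IR libraries and 19, 42 and 21 in TMAO+IR, at least 9.62-fold higher against a floor of 3 counts per library, and the deposited value rests on the substitute mean of 0.001 FPKM.

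More listed genes rose (122) than fell (27), and these sets differed in GC content and length. Only 1.17% of about 12721 tested genes were listed, which argues against a scaling factor off by the median fold change of the list, but a smaller scaling error stays open, since a shift of 0.2 on the log2 scale alone leaves 65 of the 122 at 2-fold. A GC-related or length-related bias in the libraries stays open. Higher and lower genes differed by -9.22 percentage points of GC (95% bootstrap interval -12.1 to -5.95) and by 1.06 in log2 length (0.58 to 1.32), each with a permutation p of 1e-05. Such a bias was also expected to make fold change follow GC and length among the 122 higher genes. This was not met (Spearman rho -0.0019, permutation p = 0.984 for GC, and rho -0.0573, p = 0.53 for length), though all these genes were selected on their fold change. Among 100 higher genes the deviations of single libraries from their group mean had Spearman rho values across genes, which are not independent replicates. They ran with length from -0.49 (IR replicate 3) to 0.37 (IR replicate 1) in IR, and from -0.12 to 0.11 in TMAO+IR. With GC they ran from -0.38 to 0.28 in IR and from -0.27 to 0.26 in TMAO+IR. Such a bias could give these ranges. So could any other difference of 1 library, since deviations from a shared mean push the other libraries of the group the opposite way. An effect of TMAO on long, AT-rich transcripts may equally be present, and without the unlisted genes bias and biology cannot be told apart.

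The immediate early and heat shock genes rose together. TMAO+IR replicate 2 was highest for Fos, Hsph1 and Hsp90aa1, and how far it sets this difference stays open: without it the median log2 fold change of the 11 genes was 1.05 (median SE 0.48) against 1.27, and 6 of the 11 passed. These genes deviated from their group means together, with a mean pairwise correlation of 0.752. In 10000 random sets drawn from 89 other higher genes the median was 0.52 and the 95th percentile 0.717. IR mean counts of the 11 genes ran from 69.3 for Nr4a2 to 4328 for Egr1, against median counts per listed gene of 110 to 172 in the IR libraries. Less counting noise in the abundant ones could also raise this correlation. A response that varies from library to library, such as with the extent of injury or the time between excision and freezing, could give this correlation too. It may contribute to the group difference. A response to TMAO itself stays open too, since handling was not recorded in the labels.

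Cell division genes fell. Among 51 annotation terms with at least 6 listed members, only cell division and cell cycle differed in direction from the rest of the list. Cell division had 0 higher and 6 lower genes, which were Aurkb, Cdk1, Kifc1, Nek2, Pimreg and Spc24 (Fisher's exact test, adjusted p = 0.0011). Cell cycle had 1 higher and 6 lower (adjusted p = 0.0034). The 6 lower genes are the same in both terms and include Cdk1, Aurkb and Spc24 of the cell cycle list, so these calls are not separate results. Fisher's exact test treats genes as independent. Genes of 1 process measured in the same libraries may change together, so these p-values may be too small. Terms with only higher members could not pass, since even 12 of 12 higher gave p = 0.125 before adjustment (Fisher's exact test). Fewer infiltrating leukocytes in the TMAO+IR tissue would be a candidate explanation. All 4 listed neutrophil, monocyte and macrophage markers (Mmp8, Slfn4, Ccr2 and Chil3) were higher, but so were 122 of the 149 listed genes. The unlisted markers were not analysed here and some of the listed ones are inducible, so this explanation stays open. With at least 50 counts only Spc24 of the 6 division genes is left, so neither call can be made there. Slower division in resident cells was not tested.

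Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave 149 genes past the threshold and the highest of the others gave 0, but the genes had been selected on the real split, and 10 splits are too few for a share under 0.05. Over 100 higher genes with at least 50 counts, the median deviation from the group mean was 0.35 in IR replicate 2, -0.36 in IR replicate 3 and -0.33 in TMAO+IR replicate 3. Over 17 lower genes it was 0.28 in TMAO+IR replicate 3.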
